A study of Mus musculus with 8 samples.

How the data were processed

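RNA was measured in the hippocampus of 8 mice, 4 heterozygous for a knockout of Nr2f1 and 4 wild type (WT). Per the labels' protocols, the mice were B6.129 F1 hybrids, labelled male and 3 months old. Complementary DNA was made from 10 ng of total RNA with a NuGEN Ovation kit that primes at the poly(A) tail and at random positions, then sheared to a 400 bp insert, built into TruSeq libraries and sequenced on an Illumina HiSeq. The kit does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. ERCC spike-in RNAs, synthetic transcripts of known concentration, were added as Mix 1 or Mix 2, per the labels.

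The authors deposited a table of raw read counts per Ensembl gene for all 8 libraries. Per the submitters' processing notes, FastQC, STAR 2.4.2a, HTSeq and DESeq2 were used with the builds NCBIM37 and mm9; the role and settings of each, the annotation and the strand setting are not given in the sources used here. The table held 37310 genes and 92 spike-in rows. The spike-in rows were kept out of library sizes and tests and took between 0.0431% and 0.0787% of the counts of a library. Gene symbols came from a GENCODE table made on GRCm38 and matched 32620 of the gene identifiers, among them 17106 of the 17913 genes tested. That annotation was used only for names, biotypes, chromosomes, base composition and neighbourhood, and its coordinates are not printed because the counts were made on another build.

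Counts were normalised by TMM and filtered with filterByExpr at its defaults, a minimum count of 10 and a total of 15. Genotypes were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust, with its version 4 dispersion estimate) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the root of F. Nr2f1 was also compared by an exact two-sided permutation test of its CPM (read counts scaled to the normalised library size). A set of 29 gene lists was compared with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry; list counts are given over all genes and adjusted over the list alone. Genes on the chromosome of Nr2f1, Nr2f1 left out, were compared with all other genes by Fisher's exact test, two-sided, on unadjusted p under 0.01.

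The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Nr2f1, Nr2f2 and Nr2f6 are always named. From the comparison, the 15 genes with the lowest p in each direction are named where the adjusted p is under 0.05 and the mean is at least 1 CPM; symbols of the Gm and Rik kinds and genes without a symbol are passed over. From each list, up to 4 members past 0.05 adjusted over the list alone are named. Where a pathway list, or a list past its test, had none, the 2 members with the lowest p are given as values. Some genes that the rule chose are not reported here, and no other gene took their place. Genes named outside this rule are marked as chosen after their values were seen.

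The alternatives fixed in this way were DESeq2 size factors and upper quartile scaling, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a filter of 1 CPM in 4 libraries, non-robust and older dispersion estimates, each library left out, the replicate number as a block, the run of animal numbers as a covariate, 1 surrogate variable from sva 3.50.0, and spike-in scaling. Alternatives added after the data were seen were the spike-in mix, a choroid plexus score or an ependymal score as a covariate, each mix alone, and WT libraries 1 and 3 left out together. The edgeR step was run on simulated counts with the means and depths of these libraries and 17913 genes. It recovered 41.8% of genes changed by 0.3 on the log2 scale, 65.7% of those changed by 0.6 and 84.8% of those changed by 1. Of its calls, 4.48% were unchanged genes. The simulated genes were drawn independently, with equal numbers raised and lowered, so these shares do not cover differences that many genes of a library share.

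Libraries held 58717305 to 90043971 gene counts. A count of 0 allowed up to 3 counts, between 0.0332 and 0.051 CPM by library; such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Within each genotype every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 7.42 to 25.0 over genes with at least 20 counts in the pair, so none was treated as a duplicate.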

Results

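Hippocampal RNA from 4 Nr2f1 heterozygotes and 4 wild-type (WT) mice was compared to ask which genes change when a copy of Nr2f1, a nuclear receptor that patterns the developing brain, is disrupted. Each library came from a separate animal. Total gene counts were 76154175, 87045468, 81040953 and 90043971 in WT libraries 1 to 4 and 58717305, 78721055, 88831603 and 81045253 in heterozygote libraries 1 to 4. The ratio of the spike-in ERCC-00130 to ERCC-00002 lay between 1.2 and 1.28 in odd-numbered libraries and between 0.165 and 0.186 in even-numbered ones, in both genotypes, so the spike-in mix differed by replicate number. All animals were labelled male. Xist, the RNA that coats the inactive X chromosome, lay between 463.2 and 601.4 CPM (TMM-normalised read counts scaled to library size) in the 8 libraries, and the 14 Y-linked genes in the table had 3 counts in total, all of Uty.

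Nr2f1 (ENSMUSG00000069171.7, chromosome 13) was lower in heterozygotes, at 31.3 ± 2.16 CPM (SD, n = 4) against 52.2 ± 2.07 CPM in WT (SD, n = 4), or 60.1% of the WT level. The log2 fold change was -0.73 with a standard error of 0.0511 (edgeR adjusted p = 7.32e-05). Values ran from 28.49 to 33.52 CPM in heterozygotes and from 49.49 to 54.14 CPM in WT, so the groups did not overlap. The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. Within the odd-numbered libraries the log2 fold change was -0.70 (edgeR adjusted p = 0.000752), and within the even-numbered ones -0.77 (edgeR adjusted p = 0.00468). The call was lost with spike-in scaling, where the log2 fold change was -0.64 (edgeR adjusted p = 0.897), and with the ependymal score as a covariate, where it was -0.55 (edgeR adjusted p = 0.469). The paralog Nr2f2 had a log2 fold change of 0.77 ± 0.182 (SE), at 37.7 ± 4.66 CPM against 22.1 ± 5.25 CPM (SD, n = 4 each), and did not pass the threshold (edgeR adjusted p = 0.0778). Nr2f6 differed by 0.016 ± 0.0745 (SE) on the log2 scale (edgeR adjusted p = 0.944).

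**Figure D1:**
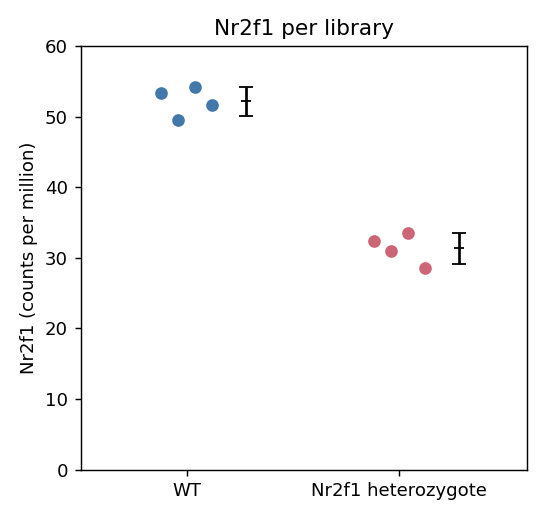
Nr2f1 in CPM (vertical axis) in 4 WT and 4 Nr2f1 heterozygote libraries; points are libraries, and the bar beside them is the mean with its SD. Heterozygote libraries sit between 28.49 and 33.52 CPM and WT libraries between 49.49 and 54.14 CPM.

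Beyond Nr2f1, most genes that passed the test were higher in heterozygotes. Of 17913 genes tested, 535 passed an edgeR adjusted p of 0.05, 469 higher and 66 lower, with a median log2 fold change of 0.74 and -0.20. More than a 2-fold change was seen for 158 higher and 3 lower genes. Yap1, a transcriptional effector of the Hippo pathway, rose to 28.8 ± 0.730 CPM from 21.2 ± 0.871 CPM (SD, n = 4 each; edgeR adjusted p = 0.00226). The tight junction gene Tjp3 rose 2.41-fold, and Postn, which encodes the matrix protein periostin, 2.23-fold. Slc38a3, a glutamine transporter gene, rose 1.36-fold. The protein disulfide isomerase gene Pdia4 rose 1.26-fold, the adaptor gene Efs 1.59-fold, the protease gene Ctsc 1.49-fold, Phactr2 1.42-fold and the axonemal gene Wdr78 1.30-fold. Tgfbr3, a TGF-beta co-receptor gene, rose 1.42-fold, Mlf1 3.10-fold and Sod3, an extracellular superoxide dismutase gene, 1.71-fold. Klk1b22 rose 2.24-fold and Zfp459 2.30-fold; both belong to families of similar genes, so the counting can split their reads. In each of these 14 genes the genotypes did not overlap, which their choice by lowest p favours. Of all tested genes 10.6% separated in this way, where chance gives 2.86% for each gene. Genes that vary together can move that share without a genotype effect, so the excess was not tested.

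Genes that fell did so by smaller amounts. Extl1 fell to 80.7 ± 2.22 CPM from 93.3 ± 0.294 CPM (SD, n = 4 each; edgeR adjusted p = 0.00682). The fold of heterozygotes over WT was 0.882 for Rapgef4, a cAMP-activated exchange factor gene, 0.885 for Pcsk2, a prohormone convertase gene, 0.850 for Gabrb2, a GABA-A receptor subunit gene, 0.837 for the adhesion gene Cadm2 and 0.905 for the chloride channel gene Clcn2. That fold was 0.832 for Cdc25b, 0.729 for Filip1l, 0.881 for Cemip, 0.903 for March7 and 0.858 for Ankrd33b. Prph, an intermediate filament gene, was at 0.572 of WT, Tdo2 at 0.659 and Zfp58, a zinc finger gene with close relatives, at 0.762. Without each library in turn, 16 of the 28 genes named above (Nr2f1 apart) kept their call every time, among them all 14 higher ones. The number of changed genes was 222 without WT library 1, 171 without WT library 3, 170 without both, and 321, 315 and 281 without heterozygote library 1, 3 or 4. Without WT library 3 the 171 were 165 higher and 6 lower, and the number of lower genes ran from 1 with spike-in scaling (184 higher) to 267 with the DESeq2 Wald test (916 higher) over the alternatives without a tissue score. The total was 557 among odd-numbered and 78 among even-numbered libraries. It was 1 with the choroid plexus score as a covariate in edgeR and 0 with the ependymal score. Of the variance of these scores, 58.7% and 77.4% in that order lay between the genotypes, so this loss does not tell tissue from genotype. With these scores 1181 and 893 genes had an unadjusted edgeR p under 0.05, against 3073 without a score. Chance alone puts a share of 0.05 of the 17913 tested genes there.

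**Figure D2:**
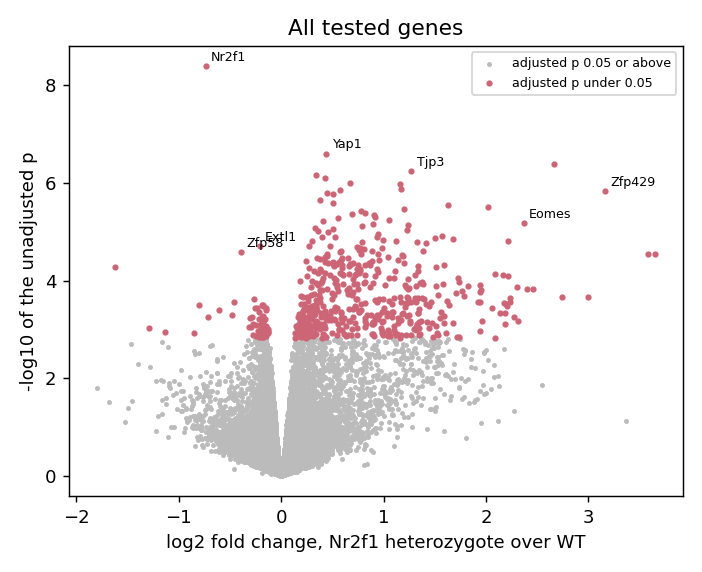
Log2 fold change of Nr2f1 heterozygotes over WT (horizontal axis) against -log10 of the unadjusted edgeR p (vertical axis) for 17913 genes, coloured where the adjusted p is under 0.05. The 469 higher genes spread to larger changes than most of the 66 lower ones.

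Markers of the choroid plexus and the ventricle lining were higher in heterozygotes. The choroid plexus list had a median log2 fold change of 1.81 over 12 genes (camera adjusted p = 6.99e-08; adjusted p = 0.318 with an estimated correlation). None of its members passed over all genes, and 10 were higher adjusted over the list alone, among them Calml4 at 3.48-fold, Sostdc1 at 2.81-fold, the water channel gene Aqp1 at 4.33-fold and Kl at 2.77-fold. All 6 ependymal genes were higher adjusted over the list alone, and 4 over all genes, namely Mia at 2.52-fold, Dynlrb2 at 3.08-fold, Rsph1 at 2.31-fold and Ccdc153 at 2.55-fold (camera adjusted p = 2.89e-06; adjusted p = 0.313 with an estimated correlation). The meningeal fibroblast list had a median of 0.87, with 0 of 9 genes past over all genes and 3 higher adjusted over the list alone, Col3a1 at 1.89-fold, Col1a2 at 1.74-fold and Igf2 at 2.75-fold (camera adjusted p = 4.75e-05; adjusted p = 0.313 with an estimated correlation). WT libraries differed among themselves in these markers. The choroid plexus score, the list's mean log2 CPM minus its mean over the 8 libraries, was -3.37, -0.19, -1.63 and 0.33 in WT libraries 1 to 4 and 1.16, 1.34, 1.15 and 1.21 in heterozygote libraries 1 to 4. Ttr, a choroid plexus transcript chosen after its values were seen, was at 44.9, 1280, 374 and 1884 CPM in WT libraries and 3831, 4201, 3812 and 3698 CPM in heterozygote libraries, and did not pass (edgeR adjusted p = 0.350). With the choroid plexus score as a covariate the meningeal list lost its call (camera adjusted p = 0.0751).

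**Figure D3:**
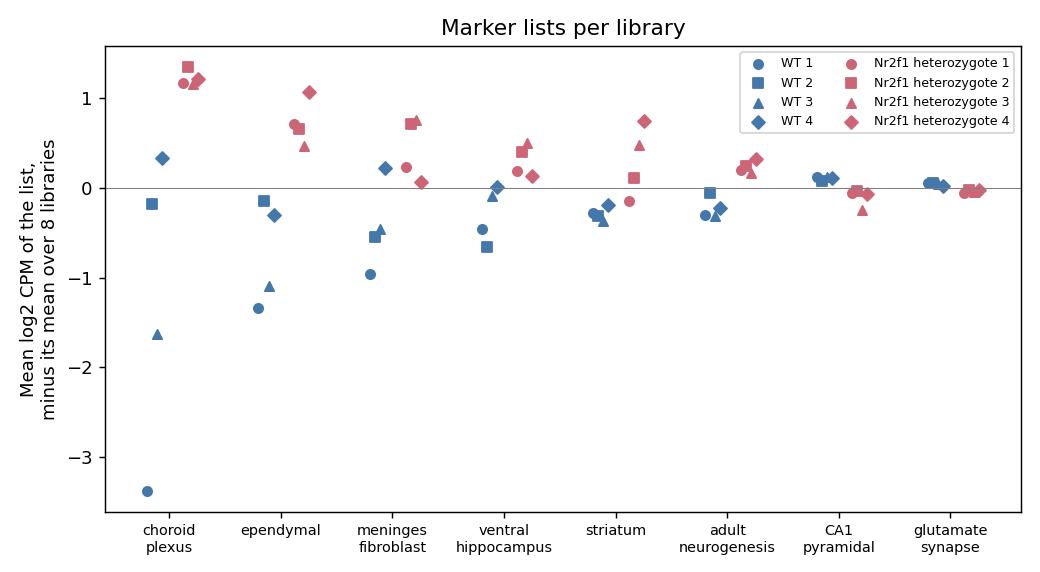
Mean log2 CPM of 8 marker lists in each library, minus the list's mean over the 8 libraries (vertical axis); colour gives genotype and shape the replicate number. Choroid plexus values spread from -3.37 to 0.33 in WT and from 1.15 to 1.34 in heterozygotes; with spike-in scaling the glutamate synapse median log2 fold change is positive and that of all genes is 0.091.

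Lists of the ventral hippocampus, striatum and thalamus were also higher, as was the choroid plexus score. Within a genotype, the order of the libraries in these lists was not that of the score. The striatal score, centred in the same way, ran from -0.37 to -0.20 in WT and from -0.15 to 0.75 in heterozygote libraries. For the choroid plexus the next sentence gives the range. The choroid plexus score lay above 0.33 in each heterozygote library and at or below it in each WT library. The ventral hippocampus list had a median log2 fold change of 0.61 (camera adjusted p = 4.75e-05; adjusted p = 0.313 with an estimated correlation). Of its 9 genes, 2 were higher over all genes, Dlk1 at 2.06-fold and the serotonin receptor gene Htr2c at 1.84-fold. Adjusted over the list alone 5 were higher, including Nr2f2 and Nnat, at 1.71-fold and 1.30-fold. Of the 9, 2 are also in another list, so those genes do not point to this region alone. Whether the other members do was not tested. Among WT libraries Htr2c, like the choroid plexus score, was lowest in library 1 (25.1 CPM) and highest in library 4 (44.4 CPM). Libraries 2 and 3 went the other way, with Htr2c at 30.4 and 37.0 CPM and scores of -0.19 and -1.63. Dlk1 was highest in WT library 3 (9.91 CPM). Striatal markers had a median of 0.73 (camera adjusted p = 0.000134; adjusted p = 0.332 with an estimated correlation), with Ppp1r1b, at 62.8 ± 11.3 CPM against 39.3 ± 4.12 CPM in WT (SD, n = 4 each), past over all genes. Adjusted over the list alone, 6 of 10 striatal genes were higher, including Adora2a at 2.81-fold, Tac1 at 1.47-fold and Drd2 at 1.86-fold; the list lost its call with the ependymal score as a covariate (camera adjusted p = 0.0858). Thalamic markers had a median of 0.22 (camera adjusted p = 0.00581; adjusted p = 0.346 with an estimated correlation), with Prkcd at 1.38-fold past over all genes and 4 of 10 higher adjusted over the list alone, including Zic1 at 2.47-fold, Tcf7l2 at a log2 fold change of 0.67 and Lef1 at 1.24-fold. The thalamic list did not pass among even-numbered libraries or without heterozygote library 2 (camera adjusted p = 0.0522 and 0.0523). The neocortex list did not pass and had a median of -0.061 (camera adjusted p = 0.782). In that list Foxp2 was 1.79-fold higher over all genes. Foxp2 and Tbr1, the latter at 0.813 of WT, were the 2 of 9 past adjusted over the list alone.

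Of 15 genes in the adult neurogenesis list, 4 rose over all genes, 5 were higher adjusted over the list alone, and 10 passed neither. The list passed with a median log2 fold change of 0.15 (camera adjusted p = 0.00345; adjusted p = 0.313 with an estimated correlation). Eomes, a transcription factor gene of intermediate progenitors, rose to 1.47 ± 0.307 CPM from 0.280 ± 0.185 CPM (SD, n = 4 each; edgeR adjusted p = 0.00436). Cdk1, a cell cycle kinase gene, rose 3.21-fold, Igfbpl1 2.20-fold and Calb2, which also marks interneurons, 1.41-fold. The list lost its call with the choroid plexus or the ependymal score as a covariate (camera adjusted p = 0.0562 and 0.514). Interneuron markers did not pass as a list (camera adjusted p = 0.0622), and did so without WT library 3 (camera adjusted p = 0.0340); 2 of 28 were higher over all genes, Dlx2 at 1.37-fold and Calb2, and 7 adjusted over the list alone, including Tac1 and Sp8 at 1.54-fold. In the list of patterning genes linked to Nr2f1, Eomes passed over all genes, Sp8 and Tbr1 joined it adjusted over the list alone, and 17 of 20 passed neither. That list had a median of -0.048 and a mean of 0.22, which differ in sign, and camera gave an adjusted p of 0.894.

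Lists of neuronal genes passed with small differences. The glutamate synapse list had a median log2 fold change of -0.071 over 43 genes (camera adjusted p = 6.05e-05; adjusted p = 0.313 with an estimated correlation), which with spike-in scaling was 0.019, or -0.072 relative to the median of all genes, moved by that scaling from -0.0056 to 0.091. None of its members passed over all genes; Cacng2 at 0.898 and Gria3 at 0.912 of WT were lower adjusted over the list alone. Voltage-gated channel genes had a median of -0.086 over 44 genes (camera adjusted p = 5.20e-05; adjusted p = 0.313 with an estimated correlation), which with spike-in scaling was 0.0039, or -0.087 relative to the median of all genes. Scn1a, a sodium channel gene, passed over all genes at 0.872 of WT, none passed adjusted over the list alone, and Cacna2d1 had a value of 0.888. With spike-in scaling neither list passed (camera adjusted p = 0.105 and 0.147). Among even-numbered libraries neither list passed (camera adjusted p = 0.0522 and 0.109), and with the choroid plexus score as a covariate the glutamate list did not (camera adjusted p = 0.0651). CA1 pyramidal markers had a median of -0.17 (camera adjusted p = 0.00993; adjusted p = 0.313 with an estimated correlation); Wfs1 at 0.846 and Mpped1 at 0.877 of WT passed over all genes, and with Ccn3 at 0.900 they were the 3 of 6 lower adjusted over the list alone. CA1 markers did not pass among even-numbered libraries (camera adjusted p = 0.137) or with spike-in scaling (camera adjusted p = 0.147). Dorsal hippocampus markers did not pass (camera adjusted p = 0.0569), and did so without WT library 2 or heterozygote library 1 or 4 (camera adjusted p = 0.0365, 0.0362 and 0.0265); Wfs1 passed over all genes and Wfs1 and Ccn3 were the 2 of 5 lower adjusted over the list alone. The GABA synapse list did not pass (camera adjusted p = 0.196), and its median of -0.048 and mean of 0.0014 differ in sign. Gabrb2 was lower over all genes. Adjusted over the list alone 3 of 23 passed, among them Gabrb2, lower, and Slc32a1, the vesicular GABA transporter gene, 1.10-fold higher.

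Markers of other hippocampal cells gave mixed results. In the CA3 and CA2 list (camera adjusted p = 0.498), Map3k15 rose 1.89-fold and Prss35 fell to 0.719 of WT over all genes; Amigo2 at 1.22-fold and Cacng5 at 1.29-fold also passed adjusted over the list alone, 4 of 15. Tdo2 was the only 1 of 11 dentate granule markers to pass, over all genes and adjusted over the list alone (list camera adjusted p = 0.215, and 0.0230 and 0.0364 without WT or heterozygote library 4). Of 12 astrocyte markers (camera adjusted p = 0.910), 0 passed over all genes and 5 adjusted over the list alone, including Slc1a2 at 0.909 and Fgfr3 at 0.875 of WT and Mlc1 at 1.10-fold and Sox9 at 1.14-fold. Mural markers passed (camera adjusted p = 0.0327; adjusted p = 0.313 with an estimated correlation), with the smooth muscle actin gene Acta2 at 1.46-fold over all genes and Acta2 and Vtn, at 1.19-fold, the 2 of 8 higher adjusted over the list alone. The mural list did not pass without WT library 2 or 4 or heterozygote library 1 or 3 (camera adjusted p = 0.103, 0.0506, 0.0589 and 0.0669), nor within either mix (0.0604 odd, 0.0695 even). Myelinating oligodendrocyte markers passed as higher with a median of 0.10 (camera adjusted p = 0.0452; adjusted p = 0.828 with an estimated correlation). The median turned to -0.082 among even-numbered libraries, where the list did not pass (camera adjusted p = 0.0678). The list passed as lower with the choroid plexus score as a covariate (median -0.20, camera adjusted p = 0.000241), with the ependymal score (median -0.37, camera adjusted p = 3.39e-07) and without WT libraries 1 and 3 (median -0.11, camera adjusted p = 0.00319). None of the 19 passed over all genes or adjusted over the list alone; Trf and Opalin had values of 1.21-fold and 1.20-fold. That list did not pass without WT library 1 or 3 or heterozygote library 1 or 2 (camera adjusted p = 0.416, 0.689, 0.174 and 0.333). Axon guidance genes did not pass (camera adjusted p = 0.910), with Slit2 at 1.21-fold and Epha5 at 0.898 of WT the 2 of 41 past adjusted over the list alone and 0 over all genes. No member of the microglia, endothelial, oligodendrocyte precursor, blood, immediate early or nuclear oxidative phosphorylation list passed over all genes or adjusted over the list alone. These lists had camera adjusted p of 0.986, 0.910, 0.910, 0.0783, 0.910 and 0.406 in that order, and blood passed without heterozygote library 4 (camera adjusted p = 0.000102). The lowest p among immediate early genes belonged to Inhba and Sik1, at 1.18-fold and 1.24-fold, and among nuclear oxidative phosphorylation genes to Atp5g1 and Ndufb10, at 1.06-fold and 1.05-fold.

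Lists that can track RNA quality also passed. Mitochondrially encoded genes had a median log2 fold change of -0.20, with 0 of 13 past over all genes and 4 lower adjusted over the list alone (camera adjusted p = 0.000416; adjusted p = 0.318 with an estimated correlation). These were mt-Nd2 at 0.873 of WT, mt-Nd1 at 0.897, mt-Atp8 at 0.361 and mt-Atp6 at 0.655; mt-Atp8 and mt-Atp6 overlap on the mitochondrial genome, so their reads are uncertain. Ribosomal protein genes had a median of 0.044, with none of 76 past over all genes or adjusted over the list alone (camera adjusted p = 0.000397; adjusted p = 0.740 with an estimated correlation), and Rps2 and Rps25 had values of 1.08-fold and 1.07-fold. The ribosomal list did not pass among even-numbered libraries, with spike-in scaling or without heterozygote library 3 (camera adjusted p = 0.976, 0.959 and 0.0755).

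Genes on chromosome 13, which carries Nr2f1, were compared with the rest because strain sequence can flank a targeted allele in a B6.129 cross. With Nr2f1 left out, 50 of 602 genes there had an unadjusted p under 0.01, against 1319 of 16503 elsewhere, an odds ratio of 1.04 with a 95% interval of 0.76 to 1.4 (Fisher's exact test, two-sided, p = 0.76). The odds ratio was 0.98 without WT library 4. Within 10 Mb the counts were 6 of 67 genes, an odds ratio of 1.13 with an interval of 0.399 to 2.61 (Fisher's exact p = 0.655). Within 20 Mb they were 19 of 200, an odds ratio of 1.21 with an interval of 0.709 to 1.95 (Fisher's exact p = 0.43). At an unadjusted p under 0.05 the odds ratios were 1.2 for the chromosome (interval 0.968 to 1.47, Fisher's exact p = 0.09), 1.03 within 10 Mb (0.502 to 1.95, p = 0.873) and 1.34 within 20 Mb (0.933 to 1.89, p = 0.0919). Of those 200 genes, 11 (5.5%) passed an edgeR adjusted p of 0.05, against 515 of 16905 elsewhere (3.05%), shares that were not tested against each other. Of the 11, Zfp459, Zfp429 and Zfp58 lie close together on GRCm38, and Zfp429, chosen after its values were seen, was at 0.827 ± 0.223 CPM in heterozygotes and 0.0933 ± 0.0491 CPM in WT (SD, n = 4 each).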

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

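In groups of 4 libraries, 246 sets of values were searched for a library far from the other 3, covering named genes, list means and total counts. The search marked 9 sets, or 3.66% of them, where chance marks about 1 in 20 and would give 12.3. None was in WT library 1. In WT, library 3 had Cacng2 at 72.3 CPM where the others had 67.8 to 68.5 CPM, and Drd2 at 3.94 CPM against 2.85 to 2.89 CPM. WT library 4 had a glutamate synapse mean of 7.17 log2 CPM against 7.2 in the others. Among heterozygotes, library 2 had Amigo2 at 28.3 CPM against 33.5 to 34.4 CPM, Acta2 at 4.65 CPM against 5.66 to 5.87 CPM and Aqp1 at 22.0 CPM against 19.3 to 19.6 CPM. The same library had a neocortex mean of 3.43 log2 CPM against 2.92 to 3.00. Heterozygote library 1 had Ndufb10 at 80.8 CPM against 78.7 to 79.0 CPM, and library 3 a CA1 mean of 6.05 log2 CPM against 6.23 to 6.26.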

How the results depend on the processing

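Alternatives with the mix, the tissue scores, each mix alone, or WT libraries 1 and 3 left out, and those of the chromosome 13 test that leave out a library, were chosen after the data were seen. Nr2f1 was lower in every alternative run, and its call ended in 2: spike-in scaling (-0.638) and the ependymal score (-0.549). The spike-in share was 0.0431% to 0.0491% in odd-numbered and 0.0713% to 0.0787% in even-numbered libraries, a spread that spike-in scaling passes on to every gene; the other loss is described with the tissue scores. Changed genes numbered 535, and 1183 with the DESeq2 Wald test and 1097 at an adjusted p of 0.1. With the animal number run they numbered 231, with spike-in scaling 185 and in even-numbered libraries 78. There were 170 without WT libraries 1 and 3, 1 with the choroid plexus score and 0 with the ependymal score. Both scores overlap with genotype, so the loss with a score does not tell tissue from genotype. With the ependymal score 893 genes had an unadjusted edgeR p under 0.05, against 3073 without a score. Leaving out a library gave 171 (WT library 3) to 767 (WT library 4); the count was 222 without WT library 1, and 321, 315 and 281 without heterozygote library 1, 3 or 4. Lists past camera numbered 14, and 7 in even-numbered libraries, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 4 by fry. The odds ratio on chromosome 13 was 0.98 to 1.3 without 1 library and turned below 1 without WT library 4. The cause was not tested for these changes. Fewer libraries were kept where some were left out, but the number kept does not by itself set the count of changed genes. That count was 171 without WT library 3, 474 without WT library 2 and 767 without WT library 4.

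Replicate numbers did not pair the samples: same-numbered libraries correlated at -0.093 to 0.027 and 0 libraries correlated best with their own number. With the replicate block 406 genes passed, 382 higher, and 16 lists.

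Of 2390 values of 92 other named genes under the alternatives, 1826 kept their direction and side of the threshold, 417 lost a call, 131 gained a call and 16 changed sign. Of 725 values of the 29 lists the numbers were 561, 57, 31 and 76. The values below are log2 fold changes, medians for lists. Spike-in scaling moved the median of all genes from -0.00556 to 0.0908, and relative to that median 0 of the 29 lists changed sign, so the 11 turns listed for it follow from this shift. With upper quartile scaling, the sign turned for immediate early genes (0.00191), microglia (0.00963), endothelial (0.00249). With limma-voom, the sign turned for immediate early genes (0.00918). With the replicate block, the sign turned for immediate early genes (0.0103). With the animal number run, the sign turned for dentate granule (0.000321), microglia (0.00335). With 1 surrogate variable, the sign turned for immediate early genes (0.00895), CA3 CA2 pyramidal (-0.0142), microglia (0.00775). With spike-in scaling, the sign turned for glutamate synapse (0.0187), GABA synapse (0.0465), immediate early genes (0.0685), voltage gated channels (0.00389), axon guidance (0.0753), Nr2f1 linked patterning (0.0486), dentate granule (0.0343), astrocyte (0.0797), microglia (0.10), endothelial (0.0899), neocortex (0.0299). In odd-numbered libraries, the sign turned for immediate early genes (0.0534), CA3 CA2 pyramidal (-0.00929), astrocyte (0.0555), microglia (0.0615), endothelial (0.0363). In even-numbered libraries, the sign turned for Nr2f6 (-0.0792), axon guidance (0.0163), nuclear OXPHOS (-0.00331), dentate granule (0.0181), myelinating oligodendrocyte (-0.0815), oligodendrocyte precursors (-0.0573). With the choroid plexus score, the sign turned for Sik1 (-0.0328), Trf (-0.12), Opalin (-0.16), axon guidance (0.00867), Nr2f1 linked patterning (0.0204), dentate granule (0.0476), dorsal hippocampus (0.0476), myelinating oligodendrocyte (-0.20), oligodendrocyte precursors (-0.0370), microglia (0.0282), endothelial (0.0536). With the ependymal score, the sign turned for Nr2f6 (-0.0328), Sik1 (-0.0394), Ndufb10 (-0.00390), Trf (-0.36), Opalin (-0.30), Sostdc1 (-0.12), Kl (-0.10), Ccdc153 (-0.18), Nr2f1 linked patterning (0.00853), myelinating oligodendrocyte (-0.37), oligodendrocyte precursors (-0.11), microglia (0.0334), endothelial (0.11), choroid plexus (-0.19), ependymal (-0.0268). Without WT libraries 1 and 3, the sign turned for Nr2f6 (-0.0233), axon guidance (0.00317), Nr2f1 linked patterning (0.00107), dentate granule (0.000510), myelinating oligodendrocyte (-0.11), oligodendrocyte precursors (-0.0307), microglia (0.00920), endothelial (0.0280). Of the turned list medians, these passed camera: Nr2f1 linked patterning with spike-in scaling (adjusted p = 0.0317), choroid plexus with the ependymal score (adjusted p = 0.0280), and myelinating oligodendrocyte with the choroid plexus score (adjusted p = 0.000241), the ependymal score (adjusted p = 3.39e-07) and without WT libraries 1 and 3 (adjusted p = 0.00319). Without 1 library each, values that changed sign ran as follows: Nr2f6 -0.0204 to 0.0932, immediate early genes -0.10 to 0.0798, axon guidance -0.0484 to 0.00149, CA3 CA2 pyramidal -0.0301 to 0.0469, dentate granule -0.12 to 6.49e-05, oligodendrocyte precursors -0.00816 to 0.0470, microglia -0.0397 to 0.0313, endothelial -0.0477 to 0.0109, neocortex -0.10 to 0.00746. The ependymal score is the mean of the ependymal list, so with that score as a covariate the list's mean is held near 0 by construction. The turns of that list and of its member Ccdc153 with that score therefore carry no result. Apart from this and the spike-in shift, the cause was not tested. Depth limits genes with few counts: 3 counts are 0.0332 to 0.051 CPM here.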

Other observations

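Genes that build motile cilia were among those that rose. Of 50 tested genes whose symbols begin with Cfap, Dnah, Rsph or Drc and a number, 22 were higher at an edgeR adjusted p of 0.05 and none lower, against 447 higher of 17863 other genes; no test is given, because these families were chosen after the values were seen. Cfap genes contributed 13 of 28, Dnah 4 of 12, Rsph 3 of 7 and Drc 2 of 3. None of 15 Ift genes, whose products carry cargo in all cilia, passed. The count of the 4 families was 5 among even-numbered libraries, 10 without WT library 1, 6 without WT library 3 and 9 without heterozygote library 4. It was 9 without WT libraries 1 and 3 together, 9 with the animal number run and 10 with spike-in scaling. In edgeR it was 0 with either tissue score as a covariate. With these scores 1181 (choroid plexus) and 893 (ependymal) genes had an unadjusted p under 0.05, against 3073 without a score. Chance alone puts a share of 0.05 of the 17913 tested genes there. Rsph1 is also a member of the ependymal list. Of the variance of the ependymal score 77.4% lay between the genotypes, and of that of the choroid plexus score 58.7%. The loss of calls with either score therefore does not tell tissue from genotype. The ependymal list, with a median log2 fold change of 1.34, was higher in the same comparison.

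The tests of Nr2f1 against tissue content, of chromosome 17 and of the sex-linked genes were chosen after the results they measure were seen. Those of other splits were not. The test of the mixes within WT was written before its own result, but after the choroid plexus scores of the WT libraries were seen. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called 535 genes, and the highest other called 3. A share of 1 in 35 is the smallest these splits can give, so they argue against chance without excluding it. The other splits mix the genotypes, so any difference between genotypes adds to their spread within groups and lowers their counts. They cannot tell genotype from a tissue difference that goes with it. The spike-in mix was balanced over the genotypes, with 2 libraries of each kind in each, and is not weighed here. A candidate explanation is more choroid plexus and ventricular wall in the heterozygote dissections. The choroid plexus score was higher in the even-numbered than in the odd-numbered WT libraries by 2.57 (heterozygotes: 0.118), and 93.3% of 465 higher genes, listed choroid and ependymal genes left out, were also higher there, against 47.9% of uncalled genes and 60.6% of the higher genes between the same mixes in heterozygotes. This share rests on 2 WT libraries against 2, and the genes counted are not independent. Any other difference that these libraries share along with the genotypes could give it too, so it does not single out choroid plexus or ventricular wall. A genotype effect on these tissues or cells, which the design names, stays open and was not tested apart from dissection.

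More such tissue is argued against as the whole cause of the lower Nr2f1. With the choroid plexus score as a covariate its log2 fold change was -0.674 ± 0.0756 (SE; edgeR adjusted p = 0.0188), against -0.73 ± 0.051 without. With the ependymal score it was -0.549 ± 0.0889 and its call ended (edgeR adjusted p = 0.469), with a larger standard error; 77.4% of the variance of that score and 58.7% of that of the choroid plexus score lay between the genotypes, so both scores overlap with genotype. Of the choroid plexus list, 1 of 12 genes is in another list and 5 exceeded 1 CPM in WT library 1, the library with the lowest score.

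For the number of lists past camera, 3 of 35 splits gave at least the real 14, and the highest other gave 17, so chance is not excluded for that number. For the odds ratio on the chromosome of Nr2f1, 20 of 35 splits gave at least the real 1.04, and the highest other gave 2.34, so chance is not excluded there either.

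High Xist and near-absent Y-linked counts in libraries labelled male are consistent with female animals: Xist was at least 463.2 CPM in each library. A Y chromosome missing from the counting reference would leave Xist low in males, and Xist reached 601.4 CPM. Neither genotype stood apart in this, and no biological explanation was tested.

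WT library 1 stood apart from the other WT libraries at 9 of 650 tested genes of chromosome 17. In the same search WT libraries 2 to 4 stood apart at 10, 9 and 8 of the 650, in that order. The number for WT library 1 was therefore not unusual among the WT libraries. At 7 of its 9 genes (77.8%) WT library 1 lay nearer the heterozygotes, against 64 of 117 such genes elsewhere (54.7%). An example, chosen after its values were seen, is H2-T22 of the major histocompatibility complex, a multigene family. H2-T22 was at 6.98 CPM in WT library 1, 11.4 to 12.3 CPM in the other WT libraries and 7.28 to 7.95 CPM in heterozygotes. A strain haplotype that segregates among these mice was a hypothesis from that sight, and its test did not pass. Of 126 genes at which WT library 1 stood apart, the 9 on chromosome 17 gave an odds ratio of 1.57 with a 95% interval of 0.699 to 3.11 (Fisher's exact adjusted p = 1 over 160 tests of libraries and chromosomes, of which 0 passed), less than the 2.26 of chromosome 19, 2.2 of chromosome 14 and 1.72 of chromosome 10. Its low choroid plexus score, opposite to the high scores of the heterozygotes, would put them on opposite sides of WT libraries 2 to 4; they lay on the same side at 8 of 9 genes (88.9%, exact 95% interval 51.8% to 99.7%), an interval that includes the 55.6% found elsewhere. Neither explanation is decided by these values; the comparison of sides was chosen after they were seen, and linked genes are not independent.

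Across 17106 genes with a value, the log2 fold change had a Spearman correlation of 0.162 with base composition and -0.0528 with transcript length; genes are not independent replicates.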
